A study of Mus musculus with 4 samples.

How the data were processed

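Messenger RNA libraries from mouse heart ventricles, prepared with a stranded poly(A) kit per the labels' protocols, were sequenced from 4 groups of WT and P2Y6 KO mice given isoproterenol or saline, with 1 library per group. Whether replicate or pooled animals stand behind a library is not stated. The authors deposited 1 table of CPM, the reads of a gene per 1000000 reads of its library, for 46603 Ensembl mouse genes, of which 24267 are above 0 in at least 1 library. Per the submitters' processing notes, reads were counted with HTSeq on GRCm38.p4 (mm10), and the aligner, the annotation release and the HTSeq settings are not given in the sources used here. Columns headed with the genotype alone were taken as the saline groups, since the other columns carry the treatment in their names.

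Each column of deposited CPM sums to 1000000, and all values above 0 are whole multiples of the smallest value in the column within 0.01 reads, so 100% of values could be returned to whole reads. In the order WT saline, WT isoproterenol, KO saline, KO isoproterenol, 1 read equals 0.03901, 0.04826, 0.04354 and 0.05327 CPM, and 20952, 20235, 20560 and 20596 genes are above 0. The 10 genes with the most reads take 29.9%, 33.2%, 31.2% and 26.5% of each library. A library with 0 reads of a gene was set to the floor of 3 reads (0.117, 0.145, 0.131 and 0.16 CPM), and the fold is then given as "at least". Gene positions and types came from GENCODE M21 (GRCm38) by Ensembl ID, for 46005 IDs and 14257 of the 14301 tested genes, and this release may differ from that of the authors.

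For each comparison of 2 libraries the ratio of recovered reads was scaled by TMM (edgeR 4.0.16), with 0.5 added to each count, and given an exact conditional (Clopper-Pearson) 95% interval. A gene was counted when the whole interval lay beyond 1.5-fold, among 14301 genes with a mean of at least 10 reads over the 4 libraries. The difference of the isoproterenol responses is the difference of both log2 ratios with a 95% counting interval from the 4 counts. TMM factors were 0.999, 0.946, 0.966 and 1.096. Calls shared by 2 comparisons were counted only for comparisons with no library in common, beside the number expected of independent lists. That number was not matched on expression, although genes with many reads have narrower intervals and are called more readily. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

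The additive fit of genotype and treatment over the 4 libraries leaves 1 residual degree of freedom per gene, with the interaction as residual. The plan named the edgeR test for counts and limma on log2(value + 1) for normalized values. Because the deposited unit is CPM, limma 3.58.1 with a trend on log2(CPM + 1), without scaling between libraries, was the reported test, and the edgeR quasi-likelihood test on recovered reads, which called 22 genes by treatment and 3 by genotype, was added after the data were seen. The intervals and the rule for named genes did treat the recovered reads as counts, the case for which the plan named edgeR. P-values were adjusted by Benjamini-Hochberg (BH) at 0.05. In a table of simulated counts (14301 genes, dispersion 0.05), the treatment fit called 0 genes when none changed, and with 200 changed genes it recovered 27% of 2-fold and 98% of 4-fold changes with 12 false calls. Apart from the changed genes, the 4 simulated libraries shared the same means, without the differences in composition or in response of the real libraries. The error rate of the unscaled fit on the real libraries is therefore not measured by it. The counting intervals were tested on reads drawn with counting (Poisson) error only, the same model that the interval assumes. They held the true ratio in 95.4% of genes, and the rule called 74% of 2-fold and 99% of 4-fold changes and 3 unchanged genes. That run checks the calculation and says nothing of spread between hearts.

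The comparisons, the tests, most alternatives, the lists and the rule for named genes were fixed before the data were examined. The rule names, in each comparison of 2 libraries and in the difference of responses, the 10 genes higher and the 10 lower whose interval bound nearest to no change is farthest from it, the 10 called genes per direction with the lowest p in the additive fits, P2ry6 and list members. A rule by the difference in log2(CPM + 1), for files without counts, shared 7 to 10 of each 10 names. Genes outside the rule that are named here for context are Rps13, Ftl1, Trim30a, Trim12c and those that differ by genotype under both treatments, chosen after their values were seen. A few genes that the rule takes in are not reported here.

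The 37 gene lists hold 492 members, of which 489 are in the table (Hbb-b1, Hbb-b2 and Paaf1 are not). They are hypertrophy and fetal program, structural extracellular matrix, matricellular and profibrotic, beta-adrenergic and cAMP signalling, calcium handling, adult sarcomere, ion channels and gap junctions, fatty acid oxidation, nuclear oxidative phosphorylation, mitochondrially encoded, glycolysis, nucleotide receptors and ectonucleotidases, inflammatory mediators, interferon-stimulated, physiological growth, cell cycle, unfolded protein and integrated stress response, heat shock, oxidative stress, glucocorticoid response, immediate early and circadian clock genes. The others are markers of macrophages, lymphocytes, neutrophils, fibroblasts, endothelial cells, mural cells, adipocytes, mesothelium, atrium, Schwann cells and glia, erythroid cells and skeletal muscle, genes flanking P2ry6, sex-linked genes and the substrain gene Nnt. The median log2 ratio of each list with at least 5 tested genes was set against 10000 random lists of the same size matched on mean expression in 20 bins, and stood apart when outside the 2.5 to 97.5 percentile, which 5% of lists of independent genes would do by chance. Members of a list can vary together, the chance rate with that correlation was not estimated, and of the 32 lists with a percentile 13 stood apart in KO against WT under saline.

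Alternatives were DESeq2 size factors (DESeq2 1.42.0), total counts and upper quartile scaling, other count filters, a limit of 2-fold on the interval or on the ratio, 10 expression bins, a pseudocount of 0.1, a fit without the second factor, limma-voom and the DESeq2 Wald test. Added after the data were seen were edgeR, limma with TMM scaling, the other ranking of names and the counts without genes within 20 Mb of P2ry6. Other software was Python 3.11.15 with SciPy 1.17.1, NumPy 2.4.6 and pandas 2.3.3, and R 4.3.3. Raw reads and heart weights were not analysed here.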

Results

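Messenger RNA was sequenced from heart ventricles of C57Bl6/J mice aged 8 to 12 weeks, either wild type (WT) or lacking P2Y6, a receptor for the nucleotide UDP (KO). The mice had received isoproterenol, an agonist of beta-adrenergic receptors that is used to provoke cardiac hypertrophy, at 50 mg/kg/day, or saline, by daily injection for 7 days. Each of the 4 groups held 1 library, and whether a library came from 1 heart or from a pool is not stated. The libraries held 25637369 reads (WT, saline), 20721472 reads (WT, isoproterenol), 22965087 reads (KO, saline) and 18771198 reads (KO, isoproterenol) in the listed genes. Transcripts of the mitochondrial genome took 24.9%, 28.9%, 26.3% and 22.5% of these reads in the same order. Levels are the deposited CPM, the reads of a gene per 1000000 reads of its library. Folds are ratios of reads between libraries after TMM scaling, given with a 95% counting interval. With 1 library per group there was no replicate check and no p-value for a comparison of 2 libraries. The intervals therefore compare those libraries and not the conditions, and they cover counting error only. A gene was counted as higher or lower when its whole interval lay beyond 1.5-fold, among 14301 genes with a mean of at least 10 reads.

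The targeted gene, P2ry6 (ENSMUSG00000048779, GRCm38 chromosome 7, 100937630 to 100974649), stood at 5.11 CPM in the WT saline library and 5.89 CPM in the WT isoproterenol library. It stood at 0.566 CPM (13 reads) in the KO saline library and 0.533 CPM (10 reads) in the KO isoproterenol library. The KO library was 8.43-fold lower (4.93 to 16.8) in saline and 12.2-fold lower (6.73 to 27.4) in isoproterenol. Isoproterenol and saline libraries did not differ in P2ry6 beyond counting error in WT (1.22-fold, 0.944 to 1.57) or in KO (1.19-fold lower, 0.488 to 3.07). Where in the gene the remaining KO reads lie cannot be read from a table of totals per gene.

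**Figure D1:**
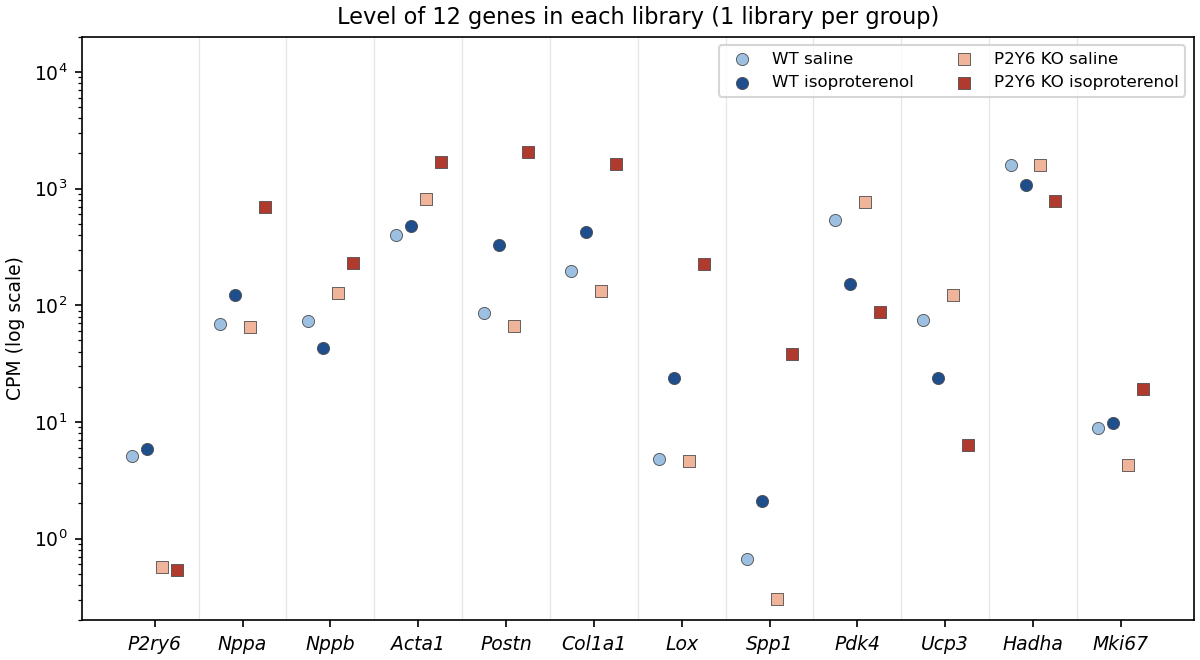
Levels of 12 genes (P2ry6, Nppa, Nppb, Acta1, Postn, Col1a1, Lox, Spp1, Pdk4, Ucp3, Hadha and Mki67) in CPM on a log axis, with 1 point per library. P2ry6 lies at 0.566 and 0.533 CPM in the KO libraries, and Postn reaches 2062 CPM in the KO isoproterenol library against 328 CPM in the WT isoproterenol library.

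The first comparison asked how WT ventricles respond to 7 days of isoproterenol. The largest ratios in the treated WT library included several genes of secreted proteins. Serpina3n (ENSMUSG00000021091), a secreted protease inhibitor of the acute phase, was higher by 11.3-fold (9.63 to 13.4) and Cthrc1, a secreted protein of injured tissue, by 27.3-fold (13.8 to 73.7). The collagen-crosslinking enzyme Lox was 5.24-fold higher (4.31 to 6.45) and the matricellular protein Postn 4.06-fold (3.87 to 4.27). Sprr1a, a stress-induced protein of cardiomyocytes, was 54.8-fold higher (23.6 to 228), the nicotinamide riboside kinase Nmrk2 6.08-fold (4.94 to 7.6) and Agt, the precursor of angiotensin, 5.6-fold (4.42 to 7.23). Lower in the treated library were several enzyme genes. The desaturase Scd4 (ENSMUSG00000050195) was lower by 60.2-fold (32.2 to 149), the thioesterase Acot1 by 8.67-fold (6.12 to 13) and Pdk4, the kinase that restrains glucose oxidation, by 3.31-fold (3.19 to 3.45). The immediate early gene Nr4a1 was 5.87-fold lower (5.08 to 6.85), Fos 4.17-fold lower (2.82 to 6.58) and Cyp26b1, which degrades retinoic acid, 9.04-fold lower (6.67 to 12.8).

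In the WT pair 123 genes were higher and 114 lower, 237 in all or 1.66% of those tested. The share higher was 51.9%, or 40.6% with total-count scaling. Among the lists fixed in advance, structural extracellular matrix had 12 of 20 genes higher and 0 lower (median log2 ratio 0.84), with Col1a1 at 2.26-fold (2.19 to 2.34) and Col3a1 at 2.59-fold (2.53 to 2.65). Matricellular and profibrotic genes had 11 of 19 higher and 0 lower (median 0.89), among them Tnc at 4.15-fold (3.17 to 5.53) and Timp1 at 3.9-fold (2.9 to 5.38). The hypertrophy and fetal program had 3 of 16 higher and 0 lower (median 0.21): Nppa, the atrial natriuretic peptide, at 1.89-fold (1.78 to 2.01), Ankrd1 at 3.27-fold (3.21 to 3.32) and Fhl1 at 3.42-fold (3.28 to 3.57). The other natriuretic peptide, Nppb, stood at 42.9 CPM in the treated and 73.3 CPM in the saline WT library, 1.62-fold lower (1.49 to 1.75) and so not counted, or 1.71-fold (1.58 to 1.85) and counted with total-count scaling. Fatty acid oxidation had 0 of 20 higher and 5 lower (median −0.34), with Fabp3 lower by 1.55-fold (1.53 to 1.58) and Ech1 by 1.54-fold (1.5 to 1.57). Glycolysis had a median of 0.26 and 1 of 15 higher, Gapdh at 1.56-fold (1.54 to 1.58), which total-count scaling took to 1.48-fold (1.46 to 1.49), so that 0 were higher. Each of these medians lay outside the central 95% of matched random lists. In the same pair fibroblast markers had a median of 0.23 (1 of 10 higher, or 0 with total-count scaling), and macrophage markers one of 0.06 (2 of 16 higher) that became −0.02 with total-count scaling. Medians of nuclear oxidative phosphorylation (−0.01), adult sarcomere (−0.08) and calcium handling (−0.07) lay within the range of random lists, although Atp2a2, the calcium pump of the sarcoplasmic reticulum, was 1.55-fold lower (1.54 to 1.56).

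The second comparison asked the same of ventricles without P2Y6. Some genes named for WT were higher in the treated KO library by larger ratios, Lox by 42.7-fold (35.4 to 52.4), Postn by 27.2-fold (25.8 to 28.6), Serpina3n by 33.5-fold (29.3 to 38.6) and Cthrc1 by 177-fold (88 to 525), while Agt had the smaller ratio there, 4.27-fold (3.28 to 5.7). Spp1, the cytokine osteopontin of macrophages and fibroblasts, was 103-fold higher (53.3 to 276), the protease inhibitor Serpinb1a 53.1-fold (40.3 to 72.9), Thbs4 36.9-fold (31.6 to 43.6) and C1qtnf3 138-fold (54.7 to 784). Sprr1a went from 2 reads to 1838, a ratio of 793 (274 to 8190), and Bmp10, a growth factor of trabecular and atrial myocardium, from 1 read to 149. Among the genes lower in the treated KO library, the mitochondrial carrier Ucp3 was lower by 21.7-fold (18.2 to 26.4), Pdk4 by 9.95-fold (9.46 to 10.5), the carboxylesterase Ces1d by 10.4-fold (9.04 to 12.1) and Scd4 by 36.4-fold (22.3 to 69.4). The sodium channel subunit Scn4b was lower by 9.92-fold (8.53 to 11.7), the potassium channel subunit Kcnv2 by 18.1-fold (11.1 to 33.8) and the myosin kinase Mylk4 by 8.57-fold (7.82 to 9.43).

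In the KO pair 1014 genes were higher and 604 lower, 1618 in all or 11.31% of those tested. The share higher was 62.7%, or 80.2% with total-count scaling, which moved the median log2 ratio of all genes by 0.18. All 20 structural matrix genes were higher (median 2.45), as were 17 of 19 matricellular genes (median 3.0). Among them were Col1a1 at 10.9-fold (10.5 to 11.4), Col3a1 at 11.2-fold (10.9 to 11.5) and Fn1 at 12.0-fold (11.4 to 12.6). The hypertrophy and fetal program had 12 of 16 genes higher and 0 lower (median 0.93). It included Nppa at 9.46-fold (8.97 to 9.98), Fhl1 at 5.86-fold (5.62 to 6.11), Xirp2 at 2.56-fold (2.51 to 2.62) and Acta1, the skeletal actin of the fetal program, at 1.84-fold (1.8 to 1.87). Atrial markers, a list that holds none of these genes, had 3 of 7 higher and 1 lower (median 0.33), and 2 of 4 skeletal muscle markers with enough reads were higher (median 0.86, too few for random lists). Cell cycle genes had 15 of 17 higher (median 1.98), with Mki67 at 3.95-fold (3.16 to 5.0) and Top2a at 5.13-fold (4.0 to 6.73). Fatty acid oxidation had 19 of 20 lower (median −1.16), or 14 with total-count scaling, with Hadha lower by 2.3-fold (2.26 to 2.34) and Ech1 by 2.93-fold (2.85 to 3.01). Nuclear oxidative phosphorylation had 4 of 20 lower and 0 higher (median −0.48), or 2 and 0 with total-count scaling, with Cox5a lower by 2.2-fold (2.11 to 2.29). Of the 13 mitochondrially encoded genes 5 were lower (median −0.71), but 4 of these 5 are among the 6 that lie under 100 CPM, of which 5 share most of their sequence with nuclear copies. Ion channels and gap junctions had 3 of 14 lower and 1 higher (median −0.41), or 2 and 2 with total-count scaling, with Kcnip2 lower by 3.54-fold (3.32 to 3.78). The medians of lists with at least 5 tested genes given so far lay outside the central 95% of matched random lists. Adult sarcomere genes had 6 of 16 lower (median −0.33), or 4 with total-count scaling, within their random range of −0.45 to 0.03. Calcium handling genes had 3 of 12 lower and 1 higher (median −0.15, or 0.03 with total-count scaling), within −0.48 to 0.11. These ranges lie mostly below 0, so a median inside them can still be lower. The nuclear oxidative phosphorylation median of −0.48 lay just past its range of −0.43 to 0.01. Atp2a2 was lower by 2.85-fold (2.83 to 2.87) and the myosin light chain Myl2 by 2.1-fold (2.08 to 2.11). Markers of other cells stood apart in the same library. Macrophage markers had 11 of 16 higher (median 1.14), including Lgals3 at 13.6-fold (10.9 to 17.3) and Ccr2 at 3.82-fold (3.09 to 4.78). Fibroblast markers had 6 of 10 higher and 1 lower (median 0.84), while the endothelial median was −0.17, or 0.01 with total-count scaling.

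The responses of both genotypes overlapped, in pairs that share no library. Of the genes beyond 1.5-fold in both, 93 were higher in both treated libraries, against 8.72 expected of independent lists, 75 were lower in both, against 4.81, and Cyp26b1 went opposite ways. The expected numbers were not matched on reads. Genes with many reads are called more readily in each pair, so part of the excess could arise from unrelated responses. Agt was higher by 5.6-fold in WT and 4.27-fold in KO, the steroid-responsive Fkbp5 by 2.78-fold (2.43 to 3.19) and 2.51-fold (2.16 to 2.93), and the joint lubricin gene Prg4 by 4.01-fold and 6.94-fold. Acot1 was lower by 8.67-fold in WT and 8.35-fold (5.89 to 12.5) in KO, and Nr4a1 by 5.87-fold and 3.34-fold (2.91 to 3.84). Of the 123 genes higher in the WT pair, 120 had the same direction in the KO pair and 78 had the larger ratio there, with medians of 1.22 in WT and 2.03 in KO. Of the 114 genes lower in the WT pair, 108 had the same direction in the KO pair and 63 had the larger ratio there, with medians of −1.25 and −1.41. Total-count scaling moves log2 ratios by −0.08 in the WT pair and 0.18 in the KO pair, so which genotype had the larger fall depends on the scaling.

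**Figure D2:**
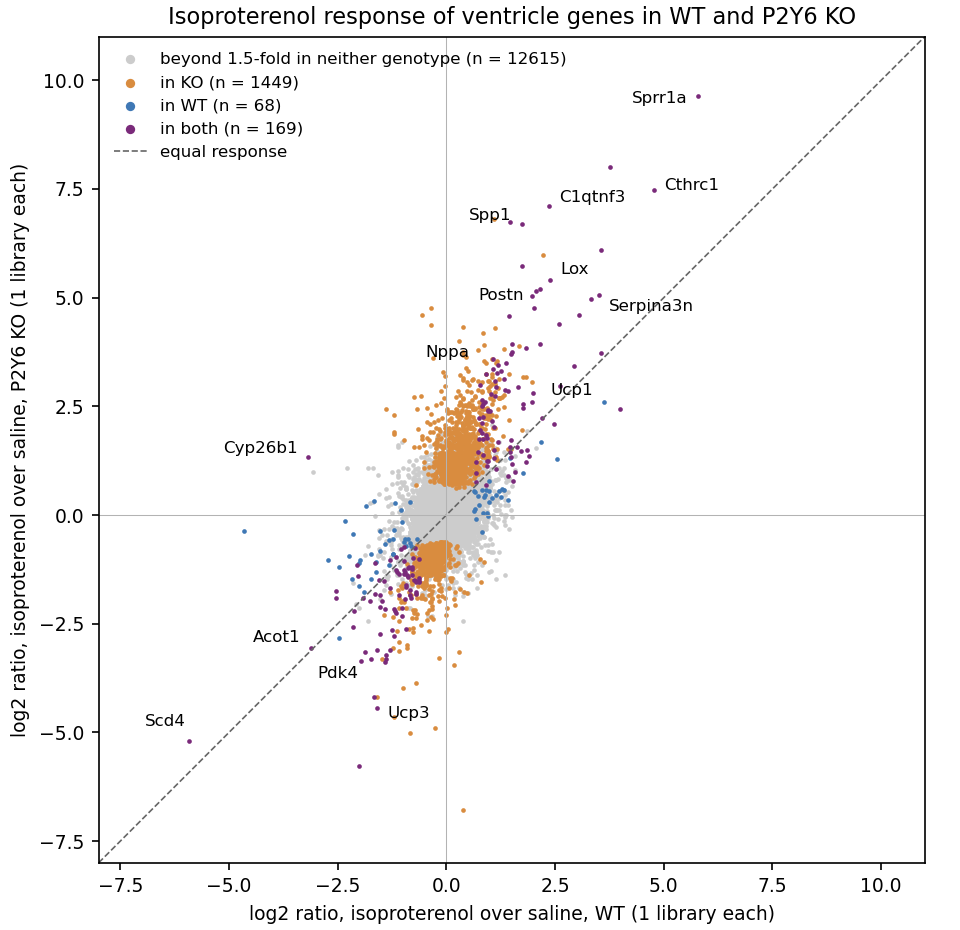
Log2 ratio of isoproterenol over saline for each of the 14301 tested genes in KO (vertical) against WT (horizontal), 1 library per group, with points coloured by the genotypes in which the gene lay beyond 1.5-fold and a dashed line of equal response. Lox, Postn and Spp1 lie above the line and Acot1 and Scd4 near it, and Cyp26b1 is the gene beyond 1.5-fold in opposite directions, at the upper left.

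The title of the series raises the question of whether loss of P2Y6 enlarges the hypertrophic response, which the difference between the responses of both genotypes addresses. Among genes with the higher ratio in KO, the log2 difference was 3.03 (2.63 to 3.42) for Lox, 2.74 (2.64 to 2.84) for Postn, 3.98 (3.41 to 4.55) for Serpinb1a, 4.96 (3.65 to 6.26) for Spp1 and 3.71 (2.92 to 4.50) for the collagen Col8a2. Among genes with the lower ratio in KO it was −2.86 (−3.15 to −2.56) for Ucp3, −1.92 (−2.20 to −1.64) for Scn4b and −1.59 for Pdk4. The interval of the difference lay beyond 1.5-fold for 548 genes with a higher and 248 with a lower response in KO, 796 in all. The share higher was 68.8%, or 92.6% with total-count scaling, which moved the median of all genes by 0.26. By list, the difference was higher for 19 of 20 structural matrix genes (median 1.73), 17 of 19 matricellular genes (2.23), 8 of 16 hypertrophy genes (0.70), 7 of 17 cell cycle genes (1.69) and 10 of 16 macrophage markers (1.12). Beside these, it was higher for 3 of 10 fibroblast markers (0.59), 3 of 7 atrial markers (0.67) and 2 of 4 skeletal muscle markers (0.96). With total-count scaling the counts were 11 for hypertrophy, 11 for cell cycle, 12 for macrophage, 6 for fibroblast and 5 for atrial genes. The atrial and cell cycle differences rest in part on the saline pair, where KO against WT had medians of −0.51 and −0.45, against 0.16 and 0.76 under isoproterenol. So do those of structural matrix (−0.43 under saline, 1.23 under isoproterenol), matricellular (−0.20 and 1.93) and fibroblast genes (−0.19 and 0.42). Hypertrophy genes had the other sign under saline (0.25, and 0.87 under isoproterenol). The difference was lower for 14 of 20 fatty acid oxidation genes (median −0.75), 10 of 13 mitochondrially encoded genes (−0.72) and 3 of 20 nuclear oxidative phosphorylation genes (−0.46), counts that became 6, 1 and 1 with total-count scaling. It was lower for 1 of 14 ion channel and gap junction genes (−0.29), 2 of 12 calcium handling genes (−0.19, or 0.08 with total-count scaling) and 1 of 15 glycolysis genes (−0.05, or 0.21 with total-count scaling), with 0 higher in each, although total-count scaling gave 1 ion channel gene and 2 glycolysis genes higher and 0 glycolysis genes lower. The design holds no error term for an interaction, so the difference was not tested.

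**Figure D3:**
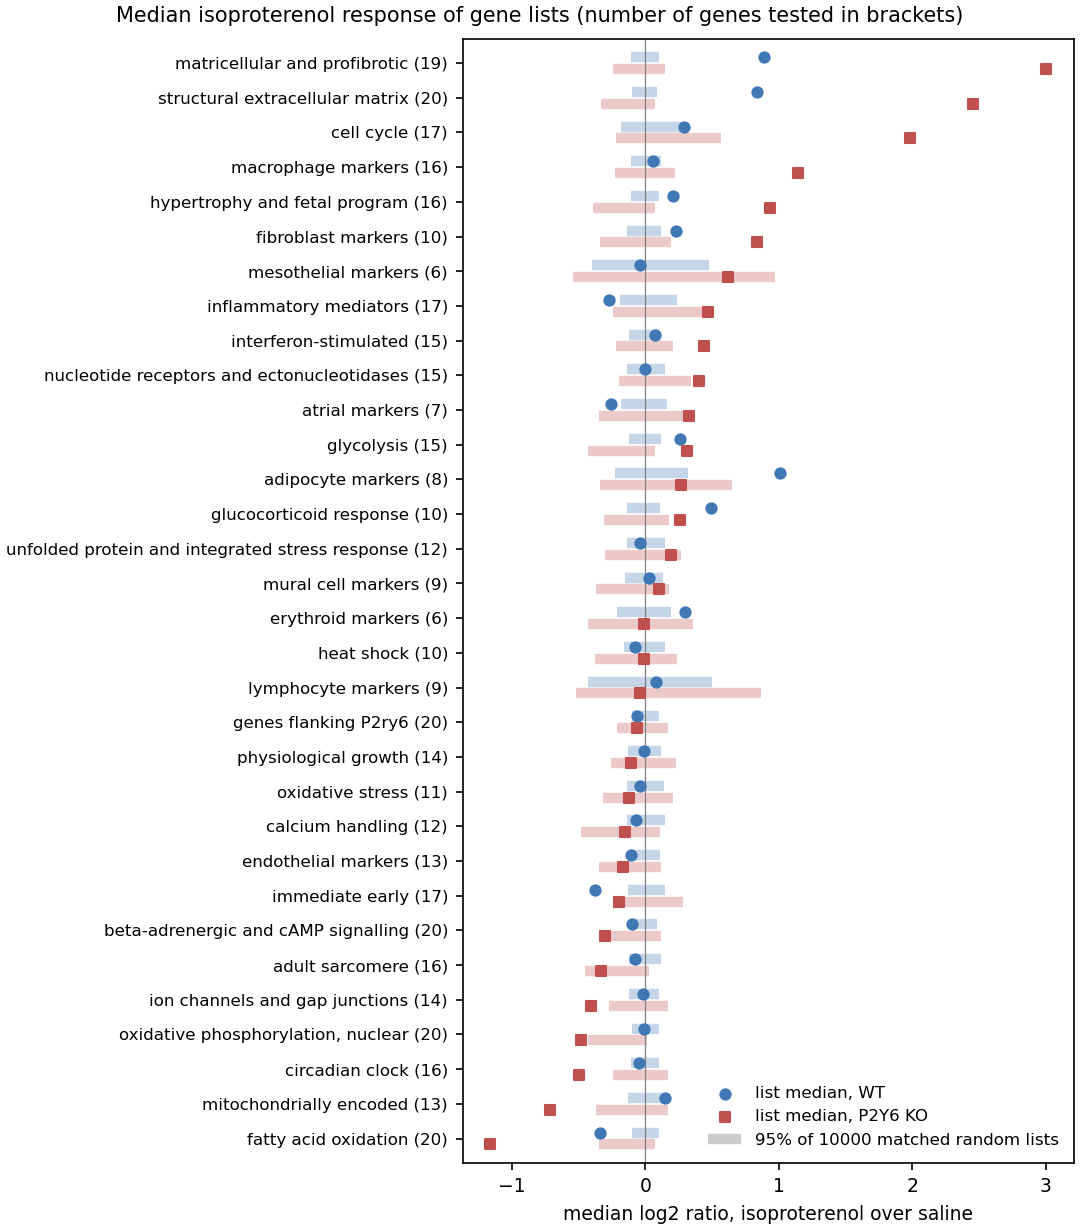
Median log2 ratio of isoproterenol over saline for the gene lists with at least 5 tested genes, as circles for WT and squares for KO, with bars for the central 95% of 10000 random lists matched on expression. Structural matrix lies at 0.84 in WT and 2.45 in KO and fatty acid oxidation at −0.34 and −1.16, and the KO medians of calcium handling (−0.15), endothelial markers (−0.17), physiological growth (−0.11), oxidative stress (−0.12), lymphocyte markers (−0.04), heat shock (−0.01), erythroid markers (−0.01) and genes flanking P2ry6 (−0.06), and the WT medians of macrophage markers (0.06), interferon-stimulated genes (0.07) and mural cell markers (0.03), change sign with total-count scaling.

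The comparison of KO with WT under saline asked what loss of P2Y6 alone changes in the ventricle. Of the hypertrophy and fetal program 3 genes were higher in the KO saline library, Acta1 (ENSMUSG00000031972) at 2.1-fold (2.05 to 2.15), the natriuretic peptide Nppb (ENSMUSG00000029019) at 1.8-fold (1.7 to 1.91) and Ankrd1 at 1.74-fold (1.72 to 1.77), while Nppa did not differ (1.01-fold lower, 0.946 to 1.09). Of genes that B and plasma cells express, Igha was higher by 6.38-fold (5.1 to 8.15), Igkc by 6.09-fold (4.73 to 8.02) and the joining chain Jchain by 5.73-fold (3.77 to 9.34). Ighm, the most abundant of these in WT, was not (1.14-fold, 0.981 to 1.34), and 0 of 9 lymphocyte markers, which include Ighm, lay beyond 1.5-fold (median 0.01, or −0.04 with total-count scaling). Angptl4, an inhibitor of lipoprotein lipase, was 3.23-fold higher (2.63 to 4.01), Scn4b 1.94-fold (1.8 to 2.09), Ucp3 1.7-fold (1.6 to 1.8) and Plekha7, a protein of adherens junctions, 4.05-fold (3.37 to 4.92). Lower in the KO library were Bmp10 by 20.5-fold (5.09 to 1230, 1 read in KO), Cyp26b1 by 3.36-fold (2.77 to 4.12) and the gluconeogenic enzyme Pck1 by 3.65-fold (2.27 to 6.39). Also lower were the lipid droplet gene Cidec by 2.89-fold (1.77 to 5.12), the elastic fibre gene Eln by 1.75-fold (1.62 to 1.9) and Mki67 by 2.02-fold (1.59 to 2.59). The ubiquitin ligase gene Trim12a, with 0 reads in KO, was lower by at least 62.9-fold from the floor of 3 reads, with a counting bound of 50.7-fold.

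Under saline 39 genes were higher and 31 lower, 70 in all or 0.49% of those tested. The hypertrophy and fetal program had 3 of 16 genes higher and 0 lower (median 0.25), and the lists of unfolded protein response, heat shock and oxidative stress had 0 on either side, although 10 of 11 oxidative stress genes had a ratio above 1 (median 0.11). Structural matrix genes had 0 higher and 1 of 20 lower, although 19 of 20 had a ratio below 1 (median −0.43). The 1 was Eln, and Col3a1, at 1.54-fold lower (1.5 to 1.59), was counted only with total-count scaling, while matricellular genes had a median of −0.20 with none beyond 1.5-fold. Cell cycle genes had 2 of 17 lower (median −0.45), adipocyte markers, which include Pck1 and Cidec, 2 of 8 lower (median −0.96), and atrial markers, which include Bmp10, 2 of 7 lower (median −0.51). The medians of the hypertrophy, oxidative stress, structural matrix, matricellular, cell cycle, adipocyte and atrial lists lay outside the central 95% of random lists, as did fibroblast markers (−0.19) and interferon-stimulated genes (−0.26), each with 0 genes beyond 1.5-fold. Fatty acid oxidation had 1 of 20 higher (Ucp3, median 0.06), and the list of physiological growth, which holds Igf1 and neuregulin pathway genes, had 0 of 14 genes on either side (median 0.00, or −0.05 with total-count scaling). Several large ratios came from genes with close copies, whose reads cannot be assigned with certainty. The pseudogene Rps13-ps1 was 46.3-fold higher (21.5 to 158), while its parent Rps13, on chromosome 7 at 116331505 and so within 20 Mb of P2ry6, stood at 88.9 CPM in KO and 108.9 CPM in WT. The pseudogene Ftl2 was 31.2-fold higher (7.83 to 1870), with 40 reads in the KO saline library but 1 in the KO isoproterenol library. Its difference was thus not shared by both KO libraries. Its parent Ftl1, on chromosome 7 at 45457944 and so outside that stretch, stood at 124.1 CPM in KO and 152.5 CPM in WT.

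The comparison of KO with WT under isoproterenol asked how the treated hearts of both genotypes compare. Several genes of the hypertrophy and fetal program were higher in the treated KO library, with Nppa (ENSMUSG00000041616) at 4.93-fold (4.73 to 5.15), or 700.5 CPM against 122.6 CPM, Nppb at 4.66-fold (4.33 to 5.01), Acta1 at 3.02-fold (2.95 to 3.09) and Xirp2 at 3.2-fold (3.12 to 3.28). Spp1 was higher by 15.4-fold (11.4 to 21.6), C1qtnf3 by 19.9-fold (13.1 to 33.2), Serpinb1a by 12.2-fold (10.5 to 14.3) and Sprr1a by 9.29-fold (8.01 to 10.9). Also higher were the collagen Col8a2 at 9.02-fold (6.72 to 12.6), Timp1 at 8.27-fold (7.09 to 9.76), Lox at 8.13-fold (7.41 to 8.95), Ltbp2 at 7.49-fold (6.9 to 8.16) and Postn at 5.42-fold (5.29 to 5.57). Lower in the treated KO library were Ucp1, the uncoupling protein of brown fat, by 12.2-fold (6.28 to 30.6), Pck1 by 6.76-fold (4.24 to 11.9) and BC023105 by 6.56-fold (5.78 to 7.49). So were Ces1d by 4.32-fold (3.72 to 5.06), Ucp3 by 4.26-fold (3.5 to 5.27), the alpha-adrenergic receptor Adra1a by 2.43-fold (1.8 to 3.34) and Pdk4 by 2.04-fold (1.92 to 2.16).

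Under isoproterenol 600 genes were higher and 258 lower, 858 in all or 6.0% of those tested. The share higher was 69.9%, or 90.3% with total-count scaling, which moved the median of all genes by 0.22 and left 112 lower. Structural matrix had 19 of 20 genes higher (median 1.23), with Col1a1 at 3.32-fold (3.25 to 3.4) and Fn1 at 4.27-fold (4.13 to 4.41). Matricellular genes had 17 of 19 higher (median 1.93) and the hypertrophy program 11 of 16 higher (median 0.87). Fatty acid oxidation had 10 of 20 lower (median −0.75), or 6 with total-count scaling (median −0.54). Hadha was lower by 1.59-fold (1.56 to 1.62) and Acadm by 1.63-fold (1.59 to 1.67), but by 1.37-fold (1.34 to 1.4) and 1.41-fold (1.38 to 1.44) with total-count scaling, where neither was counted. Mitochondrially encoded genes had 8 of 13 lower (median −0.78), 6 of which are those under 100 CPM. With total-count scaling 4 were lower, all under 100 CPM, and mt-Co1 went from 1.53-fold (1.52 to 1.53) to 1.32-fold (1.31 to 1.32) lower. Nuclear oxidative phosphorylation had 2 of 20 lower (median −0.47), or 0 with total-count scaling. Ion channels and gap junctions had 1 of 14 lower (median −0.39, Kcnip2 by 2.33-fold, 2.17 to 2.5). Inflammatory mediators had 3 of 17 higher (median 0.74), or 7 with total-count scaling, with Cxcl10 at 3.83-fold (2.37 to 6.73) and Lcn2 at 3.95-fold (2.92 to 5.51). Oxidative stress genes had 3 of 11 higher (median 0.36), with Gpx3 at 2.54-fold (2.44 to 2.65), and cell cycle genes 3 of 17 higher (median 0.76), or 9 with total-count scaling. Each of these medians lay outside the central 95% of random lists. Adult sarcomere genes had 5 of 16 lower (median −0.24), or 1 with total-count scaling, and calcium handling genes 2 of 12 lower (median −0.08, or 0.13 with total-count scaling). Atp2a2 was lower by 1.78-fold (1.77 to 1.79) and Hrc by 1.94-fold (1.89 to 1.99). Beside these, macrophage markers had 11 of 16 higher (median 1.0) and fibroblast markers 2 of 10 higher and 1 lower (median 0.42), or 3 and 0 with total-count scaling, while endothelial markers had 0 on either side (median −0.11, or 0.11 with total-count scaling). Adipocyte markers, which include Ucp1 and Pck1, had 4 of 8 lower (median −1.33, outside the central 95% of random lists), or 3 with total-count scaling. Beside the hypertrophy program, 2 of 4 skeletal muscle markers with enough reads were higher (median 0.99, too few for random lists).

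Genotype differences seen under both treatments, in pairs that share no library, numbered 24. In both, 12 genes were higher in KO, against 1.64 expected of independent lists, and 12 lower, against 0.56, and 7 genes went opposite ways. These expected numbers too were not matched on reads. Acta1, Nppb, Igha, Igkc and the GABA transaminase gene Abat (1.83-fold, 1.58 to 2.12, and 1.73-fold, 1.51 to 1.99) were higher. Pck1, Cidec, the beta globin Hbb-bt (2.63-fold, 2.28 to 3.05, and 2.38-fold, 2.11 to 2.69) and Cyp2e1 were lower. On chromosome 7 within 20 Mb of P2ry6 lay 11 of the 24, or 10 without P2ry6 itself, where 0.43 were expected from the share of tested genes there (254 of 14257). In this stretch Plekha7 (ENSMUSG00000045659, GRCm38 chromosome 7, 116123485 to 116308376) was 4.05-fold and 4.37-fold (3.58 to 5.4) higher and Fah, the last enzyme of tyrosine breakdown, 1.73-fold (1.54 to 1.94) and 1.85-fold (1.56 to 2.19) higher. Trim12a (ENSMUSG00000066258, GRCm38 chromosome 7, 104299894 to 104315466) had 0 reads in both KO libraries against 8.5 CPM and 11.5 CPM in WT. Gvin1 and Mogat2 also had 0, at least 15.9-fold and 9.23-fold lower under saline from the floor of 3 reads, with counting bounds of 12.5-fold and 7.08-fold. The neighbouring family members Trim30a (17.6 CPM in WT and 17.0 CPM in KO under saline) and Trim12c (16.1 and 20.5 CPM) were not beyond 1.5-fold. The 20 tested genes of the list flanking P2ry6 had a median of 0.02 under saline (−0.03 with total-count scaling) and −0.10 under isoproterenol (0.11 with total-count scaling). Of these Ucp3 was higher under saline, and under isoproterenol the uncoupling protein Ucp2 was higher by 2.43-fold (2.28 to 2.59) and Ucp3 was lower.

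**Figure D4:**
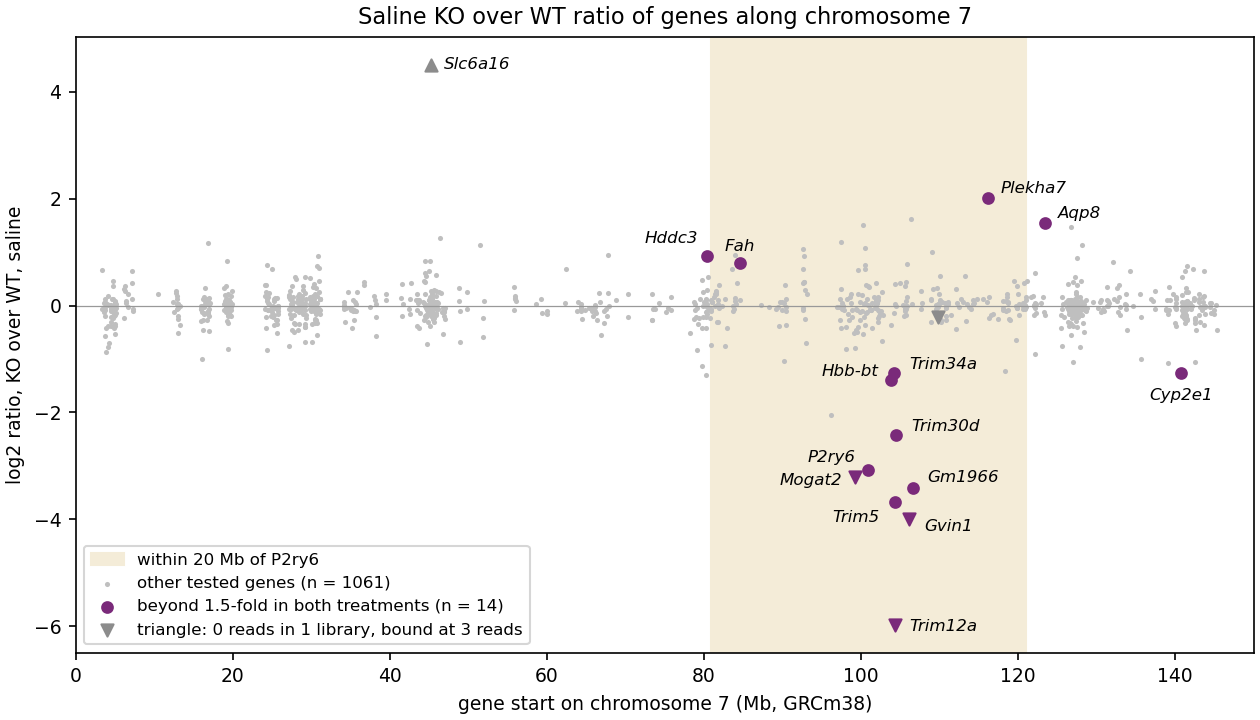
Log2 ratio of KO over WT under saline for tested genes along chromosome 7 (gene start, GRCm38), with the stretch within 20 Mb of P2ry6 shaded. Named are the 14 genes beyond 1.5-fold in both treatments and Slc6a16, which was higher in KO under saline only. Triangles mark genes at their bound, with 0 reads in KO or, as for Slc6a16, in WT. Of the named genes 11 lie in the shaded stretch, 9 of them lower in KO and 2 higher.

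An additive fit over all 4 libraries asked which genes follow the treatment in both genotypes. By limma on log2(CPM + 1), Serpina3n rose by 4.17 on the log2 scale (SE 0.283, BH adjusted p = 5.24e-08) and Scd4 fell by 4.08 (SE 0.261, BH adjusted p = 3.79e-08), each with the same direction in both genotypes. Also called by limma and by edgeR, with the same direction in both genotypes, were Prg4 (log2 change 2.39), Fhl1 (2.20), Sprr1a (4.82), Nmrk2 (3.29), Cthrc1 (4.13), Agt (2.03), Acot1 (−2.47) and Nr4a1 (−2.01). In all limma called 368 genes, 242 higher and 126 lower, with BH adjustment, and 1865 at an unadjusted p under 0.05. The edgeR fit on the recovered reads called 22, 15 higher and 7 lower, all among those of limma, and 2171 at an unadjusted p under 0.05. Structural matrix had 19 genes higher by limma over all genes and 20 adjusted over the list alone, and by edgeR 0 and 19. Matricellular genes had 13 higher by limma and 16 adjusted over the list alone (1 and 16 by edgeR), and fatty acid oxidation 9 lower and 15 adjusted over the list alone (0 and 7). The hypertrophy program had 3 higher and 13 adjusted over the list alone (1 and 3), and cell cycle genes 1 and 13 (0 and 6). The fit leaves 1 residual degree of freedom, takes any difference of response between genotypes as error and measures spread between these libraries, not between animals. The limma count came from CPM left unscaled between libraries. Without scaling, the difference of responses had a median of 0.26 over all genes, against −0.0 with TMM. The fit takes that difference as error, so the residuals of the unscaled fit hold this offset between libraries. The count of 368 was obtained with that offset in place. With TMM scaling limma called 1 gene by treatment, with 2011 at an unadjusted p under 0.05, and the cause of this change was not tested.

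For genotype over both treatments, limma called 14 genes, 6 higher and 8 lower in KO, with 586 at an unadjusted p under 0.05, and edgeR called 3 of these, with 519 at an unadjusted p under 0.05. Trim12a fell by 3.45 on the log2 scale (SE 0.257, limma BH adjusted p = 5e-07, edgeR BH adjusted p = 0.0136) and Plekha7 rose by 1.98 (SE 0.235, limma BH adjusted p = 0.000375, edgeR BH adjusted p = 0.0136), with the same direction under both treatments. Rps13-ps1 (ENSMUSG00000066362, GRCm38 chromosome 8, 87047689 to 87048226), a processed copy of Rps13, was the third, at 3.66 (SE 0.283, limma BH adjusted p = 5e-07, edgeR BH adjusted p = 0.0108), higher in both KO libraries. By limma alone Igkc, Igha, Acta1 and Nppb were higher, and P2ry6, Gvin1, Trim5, Trim30d, Pck1, Hbb-bt and the triglyceride enzyme Dgat2 lower. P2ry6 fell by 2.07 (limma BH adjusted p = 0.000431, lower in both KO libraries), with an edgeR BH adjusted p of 0.066. The hypertrophy program had 2 genes higher by limma over all genes and 12 adjusted over the list alone (0 and 6 by edgeR), and adipocyte markers 1 lower and 4 adjusted over the list alone (0 and 4). The tools differed most for matricellular and profibrotic genes, with 0 higher by limma over all genes and 16 of 19 adjusted over the list alone, against 0 and 1 by edgeR. Structural matrix had 0 and 2 higher (0 and 0 by edgeR). Neither matrix list was higher in KO under both treatments, since 3 of 19 matricellular and 1 of 20 structural matrix genes had a ratio above 1 under saline, against 18 and 20 under isoproterenol. With TMM scaling limma called 0 genes by genotype, with 412 at an unadjusted p under 0.05, and 8 of the 14 lie within 20 Mb of P2ry6.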

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

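The tests of the larger response in the KO pair and of the gathering on chromosome 7 were chosen only after the result was seen, while those of the mitochondrial genes were written before theirs. Of the values in the next paragraph, Cyp26b1 met a rule fixed before the data were examined, and the check behind the other 3 genes was applied afterwards.

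Cyp26b1 went opposite ways under isoproterenol in the genotypes, 9.04-fold lower (6.67 to 12.8) in WT and 2.53-fold higher (2.05 to 3.14) in KO, a log2 difference of 4.51 (3.97 to 5.05). Ucp3, a neighbour of P2ry6 on chromosome 7, was 1.7-fold higher in KO under saline and 4.26-fold lower under isoproterenol, a log2 difference of −2.86 (−3.15 to −2.56). Scn4b was 1.94-fold higher and then 1.95-fold lower (1.62 to 2.36), or 1.68-fold (1.4 to 2.03) and no longer beyond 1.5-fold with total-count scaling, a difference of −1.92 (−2.20 to −1.64). Eln was 1.75-fold lower under saline and 2.33-fold higher (2.21 to 2.47) under isoproterenol, a difference of 2.03 (1.89 to 2.17). None of these differences was tested, since each group holds 1 library.

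The isoproterenol response was larger in the KO pair than in the WT pair, with 1618 against 237 genes beyond 1.5-fold. A lower share of cardiomyocyte RNA in the treated KO library, if it raised markers of all other cells alike, would leave the fibroblast and endothelial medians close. In the KO pair the fibroblast median exceeded the endothelial median by 1.01 on the log2 scale (bootstrap over genes, 0.57 to 1.52). More fibroblasts with no change per cell would raise matrix genes only as far as fibroblast markers, and the structural matrix median exceeded theirs by 1.61 (1.04 to 2.57). Neither test decides why the response was larger in KO, since both used the KO pair alone. The WT pair had the same order of medians (structural matrix 0.84, fibroblast 0.23, endothelial −0.11), and the bootstrap does not measure spread between hearts. A difference between hearts unrelated to genotype cannot be told apart from loss of P2Y6 with 1 library per group. It could lie in the treated hearts, such as the dose that reached them, the severity of injury or the hour of harvest, or in the saline hearts. The hour is not given in the labels. Circadian clock genes had a median of −0.55 in KO against WT under isoproterenol and −0.06 under saline, and the cause was not tested. An amplified response in KO hearts may be the reason but stays untested, as do more of the activated fibroblasts or macrophages.

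Genes that differ by genotype under both treatments gather on chromosome 7, where 11 lie within 20 Mb of P2ry6, or 10 without P2ry6 itself, which is there by design. Random lists of 24 genes held at most 4 there in 10000 draws, and the fullest other window of that width held 2, so a chromosome segment carried with the targeted allele from another strain may account for them. Loss of P2Y6 acting on single genes regardless of position would place 0.43 there, against 10 without P2ry6. This argues against such an effect as the source of the gathering. The expectation and the random lists place each gene on its own, while Trim34a, Trim5, Trim12a and Trim30d are neighbouring members of a family. An effect of P2Y6 loss on such a cluster as a whole is therefore not excluded. Nor does the argument cover the 13 genes elsewhere, 1 of which, Rps13-ps1, may draw reads of its parent Rps13 inside the window. Of these 13, Hddc3, Aqp8 and Cyp2e1 also lie on chromosome 7, at −20.6 Mb, 22.5 Mb and 39.8 Mb from P2ry6, so the split depends on the limit of 20 Mb. Fitting the first account, neighbours such as Trim12a lie at 0 reads beside Trim30a and Trim12c at WT levels, but reads of this gene family can be shared among its copies, and neither the strain of the targeted cells nor sequence variants were available. The treatment gives a control, since 5 of the 168 genes shared by both isoproterenol responses lie in the window against 2.99 expected.

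Mitochondrially encoded genes lie at 2 separate levels, 7 between 6352 and 115213 CPM and 6 (mt-Atp6, mt-Atp8, mt-Co2, mt-Co3, mt-Nd3 and mt-Nd4l) between 1.76 and 82.4 CPM. Gene length does not account for this, since the low mt-Co3, at 784 bases, is longer than the high mt-Nd6, at 519 bases. Reads shared with nuclear copies could do so, since 5 of the 6 low genes have at least 90% of their 50-base stretches in transcripts of nuclear genes, but it stays open. The exception among low genes is mt-Atp8 at 0%, while mt-Co1 (51.1%) and mt-Nd4 (62.2%) are high, and only annotated transcripts were searched, as no genome sequence was used here. No biological explanation was tested, and the list median of mitochondrially encoded genes rests in part on these 6 genes.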

How the results depend on the processing

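Of the alternatives here, edgeR, limma with TMM scaling and the counts without genes near P2ry6 were chosen after the data were seen. The 7 counts of genes beyond 1.5-fold, both directions together, stayed within 1.5 times their value under DESeq2 size factors, upper quartile and total-count scaling and without a filter beyond 1 read. With a mean of at least 50 reads 6 did so, and KO against WT in saline gave 44 genes. The split by direction moved more. With total-count scaling the difference of responses went from 548 higher and 248 lower to 1062 and 85. KO against WT in isoproterenol went from 600 and 258 to 1044 and 112. An interval beyond 2-fold left 84 genes for isoproterenol in WT, 701 in KO, 31 for KO against WT in saline, 283 in isoproterenol and 265 for the difference of responses, with 59 shared by both genotypes and 14 by both treatments, as a stricter limit must. A point ratio of at least 2-fold without an interval gave 413 genes for isoproterenol in WT, 239 for KO against WT in saline, 1289 for the difference of isoproterenol response between genotypes and 58 shared by both treatments, a setting that admits genes with few reads. Without genes near P2ry6 the genotype difference shared by both treatments was 13 genes and the limma genotype count 6. In the same setting KO against WT in saline gave 56 genes and KO against WT in isoproterenol 826.

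The counts of the additive fit moved with most settings. For treatment and genotype, limma gave 647 and 60 genes with a pseudocount of 0.1, 562 and 44 with a CPM of at least 1 in any library, and 965 and 195 with no filter. It gave 2 and 1 with DESeq2 size factors, 2 and 3 with upper quartile scaling, 1 and 0 with TMM and 1 and 0 with no covariate, where 1553 and 121 genes had an unadjusted p under 0.05. On recovered reads edgeR gave 22 and 3, limma-voom 22 and 4, and the DESeq2 Wald test 176 by treatment, while its 13 by genotype and the 432 and 16 of limma with a mean of at least 50 reads were close to the reported counts. In the unscaled limma fit the prior had 18 degrees of freedom in all and the median residual SD was 0.144, against 4.77 and 0.117 with TMM. No fit held the prior fixed while the scaling changed, and the cause was not tested for any of these settings. Leaving out a library leaves 0 residual degrees of freedom, so no such test was made, and groups under 3 samples allow no other splits. No paired analysis was possible because the labels carry no replicate numbers.

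Among medians of lists and named genes, 260 values kept their direction and stayed in their interval or on their side of the random lists under DESeq2 size factors. Under total counts 250 stayed in their interval or on their side of the random lists, but 30 of these, list medians, changed sign. Another 10 values, of named genes, kept their sign but left their interval. With a mean of at least 50 reads 138 list medians stayed on their side, of which 2 changed sign, 3 came to stand apart and 4 no longer did. With 10 expression bins 158 stayed and 2 came to stand apart. Of calls of list members and named genes in the 4 comparisons of 2 libraries, total counts removed 7 higher and 52 lower and added 46 higher and 5 lower, with 31 of the lower ones removed in KO against WT in isoproterenol. No result reversed in the sense of a called value with the other sign. Depth limits genes under the floor of 3 reads, and simulated 2-fold changes were called in 74% of genes by the interval and 27% by the treatment fit.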

Other observations

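The groups of genes described here were fixed before the data were examined, and no test was added for them. Clock genes differed in the treated KO library. Of 16 circadian clock genes, 5 were lower and 1 higher in the KO pair (median −0.50) and 7 lower and 1 higher in KO against WT under isoproterenol (median −0.55, difference of responses −0.50), against −0.05 in the WT pair and −0.06 under saline. With total-count scaling 3 were lower and 2 higher in the KO pair and 4 lower and 2 higher in KO against WT under isoproterenol. Arntl, the core activator of the clock, was 4.5-fold higher (3.44 to 6.06) in the treated KO library than in the treated WT library, while its antiphase partners Per1 and Ciart were lower by 2.3-fold (2.1 to 2.54) and 2.61-fold (2.16 to 3.18). The hour of harvest is not given in the labels. Immediate early genes had 6 of 17 lower in the WT pair (median −0.38) and 4 lower, or 2 with total-count scaling, and 1 higher in the KO pair (−0.20), with a median of 0.12 under saline and 0.52 under isoproterenol for KO against WT, where 5 were higher, among them Egr1 at 2.15-fold (1.85 to 2.52) and Atf3 at 2.65-fold (1.97 to 3.65). Glucocorticoid response genes had 5 of 10 higher and 1 lower in the WT pair (median 0.49) and 3 higher and 2 lower in the KO pair (0.26), with −0.14 under saline and −0.40 under isoproterenol, where Zbtb16 was lower by 2.8-fold (2.49 to 3.15).

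Fat, blood and other tissue markers also differed between libraries. Adipocyte markers had 3 of 8 higher in the WT pair (median 1.01), with Cidea at 2.82-fold (2.56 to 3.12) and Plin1 at 2.39-fold (1.53 to 3.85), which total-count scaling took to 2.26-fold (1.44 to 3.65) and out of the count, and 1 on each side in the KO pair (0.27), and 4 were lower in KO against WT under isoproterenol (median −1.33). Ucp1 stood at 0.39 and 4.73 CPM in the WT libraries (saline, isoproterenol) and 0.0435 and 0.426 CPM in the KO libraries. Erythroid markers had 0 on either side in the WT pair (median 0.30) and in the KO pair (−0.01, or 0.17 with total-count scaling), 1 of 6 lower under saline (−0.31) and 2 lower under isoproterenol (−0.59), where Hba-a2 was lower by 1.75-fold (1.51 to 2.03), or 1.51-fold (1.3 to 1.75) and not counted with total-count scaling, and the globin genes are near-identical copies. Atrial markers had 1 of 7 higher in the WT pair (median −0.26), 3 higher and 1 lower in the KO pair (0.33), 2 lower under saline (−0.51) and 1 higher under isoproterenol (0.16), with Myl4 lower by 1.62-fold (1.51 to 1.74) under saline. Of 4 skeletal muscle markers with enough reads, 2 were higher in the treated KO library, Myl1 at 3.76-fold (3.4 to 4.16) and Tnnt3 at 20-fold (9.62 to 59.9) over saline. Mural markers gave medians of 0.03 (−0.05 with total-count scaling), 0.10, −0.11 and −0.03 (0.18 with total-count scaling) in the WT pair, the KO pair, saline and isoproterenol, with Cnn1 higher by 3.35-fold (2.74 to 4.13) and Abcc9 lower by 2.27-fold (2.19 to 2.36) in the KO pair.

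Endothelial markers had medians of −0.11 in the WT pair and −0.04 under saline. The 6 mesothelial markers had medians of −0.04, 0.62, 0.12 and 0.66 in the WT pair, the KO pair, saline and isoproterenol, all within the range of random lists, with 1 higher in the KO pair, Msln at 2.51-fold (1.73 to 3.73). Lymphocyte markers had 0 of 9 on either side in the 4 comparisons, with medians of 0.08, −0.04, 0.01 and −0.07, of which the last 3 change sign with total-count scaling (to 0.14, −0.04 and 0.14), and Ighm stood between 9.7 and 17.4 CPM. Neutrophil (4 tested) and Schwann and glial markers (4 tested) had 0 genes beyond 1.5-fold in the 4 comparisons, with medians in the KO pair of 0.51 and −0.34.

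Beta-adrenergic and cAMP genes had 0 of 20 on either side in the WT pair (median −0.10) and 1 higher and 2 lower in the KO pair (−0.30, outside the range of random lists), with the receptor kinase Grk5 higher by 2.17-fold (1.96 to 2.4) and Adra1a lower by 4.76-fold (3.64 to 6.39). In KO against WT this list had a median of −0.00 under saline, with Gnas higher by 1.83-fold (1.53 to 2.2), or 1.77-fold (1.48 to 2.12) and not counted with total-count scaling, and of −0.19 under isoproterenol (0.02 with total-count scaling). Nucleotide receptors and ectonucleotidases had 1 of 15 genes higher in the KO pair (median 0.40) and 1 in KO against WT under isoproterenol (0.18), in both cases Panx1, a channel that releases nucleotides, at 4.58-fold (3.29 to 6.63) and 2.55-fold (1.92 to 3.44), and a median of −0.00 in the WT pair and −0.01 under saline. Inflammatory mediators had 0 of 17 beyond 1.5-fold in the WT pair (median −0.27) and 4 higher in the KO pair (0.47), and interferon-stimulated genes 2 of 15 higher in the KO pair (0.44), with Mx1 at 3.07-fold (2.12 to 4.6), against a WT median of 0.07 (−0.01 with total-count scaling). Under isoproterenol interferon-stimulated genes had 1 on each side in KO against WT (median 0.22). Physiological growth genes had 1 of 14 higher and 1 lower in the KO pair (median −0.11, or 0.07 with total-count scaling), Igf1 at 3.21-fold (2.84 to 3.64) and Cebpb lower by 2.23-fold (1.66 to 3.05), or 1.96-fold (1.46 to 2.69) and not counted with total-count scaling.

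Stress lists gave small medians in the KO pair, 0.19 for the unfolded protein and integrated stress response (1 of 12 higher, Pdia4 at 1.7-fold, 1.55 to 1.88), −0.01 for heat shock (0.18 with total-count scaling, 1 of 10 lower) and −0.12 for oxidative stress (0.06 with total-count scaling, 4 of 11 higher). In KO against WT under isoproterenol the unfolded protein list had 2 higher and 1 lower (median 0.37) and heat shock 2 higher (0.24), with Hsp90aa1 at 1.84-fold (1.73 to 1.96) and Hspb1 at 1.87-fold (1.76 to 1.99). Glycolysis had 2 of 15 higher and 1 lower in the KO pair (median 0.31), with Pfkp at 2.16-fold (2.04 to 2.29), and 1 on each side in KO against WT under isoproterenol (−0.01, or 0.20 with total-count scaling). Of 4 sex-linked genes with enough reads 0 lay beyond 1.5-fold, with Ddx3y between 72.8 and 85.7 CPM and Xist at most 0.195 CPM, levels of male tissue in all 4 libraries. Nnt, which carries a deletion in the C57BL/6J substrain, stood at 511.9, 388.1, 505.5 and 277.1 CPM (WT saline, WT isoproterenol, KO saline, KO isoproterenol), and a total per gene does not show which exons the reads cover. Cpt1b was listed at 2.45 to 6.08 CPM, against 115.7 to 244.1 CPM for Cpt2, and read-through transcripts with Chkb are known to overlap it.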
